A study of Homo sapiens
Mus musculus and Mus musculus and Homo sapiens with 16 samples.

How the data were processed

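RNA from cultures of the human mantle cell lymphoma line Jeko-1 and the mouse bone marrow stromal line MS-5 was measured in 16 libraries, 4 in each of 4 groups. Per the labels' protocols, 500000 MS-5 cells were seeded in dishes of 10 cm 24 h before 5000000 Jeko-1 cells were added, and RNA was taken after 24 h from stroma alone, lymphoma cells alone, and the adherent and suspension fractions of the co-culture. Polyadenylated RNA was made into libraries with a TruSeq kit, per the labels.

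The authors deposited whole-number read counts per gene in a human and a mouse table, each with a column for every library, a gene symbol and an Entrez Gene ID, not normalized. The submitters' processing notes name TopHat2 2.0.11, Bowtie2 2.2.2, SAMtools 0.1.19 and DESeq 1.16.0, with the builds hg19 (GRCh37) and mm10 (GRCm38). How reads were assigned to a species, how reads that fit several places were treated and how genes were counted are not given in the sources used here. These steps matter in a mixed library: a read from a conserved stretch can be credited to the wrong species, and a read from a gene with close copies can be dropped or divided. Groups and replicate numbers came from the sample titles, and 0 columns were left unused.

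The size of cross-species error was estimated from single-species cultures. The expected mouse-derived count of a human gene in ADH or SUSP was its mean count in the MS-5 libraries divided by the mouse total there, times the mouse total of the library, and for mouse genes the same was done from SEP. For mouse genes the estimate rests mostly on SEP replicate 2, which had 65116 mouse counts against 5047 to 6639 in the other SEP libraries. Of 11346 human genes tested, 27 had an expected share of 10% or more in a co-culture library, with a median over genes of 0.259%, and of 10761 mouse genes 1 did, with a median of 0.174%.

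Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, libraries scaled by the trimmed mean of M values (TMM), and groups compared with the quasi-likelihood test (glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. The human fit held the 12 libraries with Jeko-1 cells, so that the 3 groups shared an estimate of the spread, and the mouse fit the 8 MS-5 and ADH libraries. Standard errors were derived from the log2 fold change and its F statistic. Gene lists, 17 human and 19 mouse, were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, which tests whether members move on balance in a direction without comparing them with other genes. List p-values were adjusted over the human lists and comparisons together and over the mouse lists. The groups, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where said.

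Named genes followed a rule. Per comparison these were the 6 rising and 6 falling genes of largest fold among called genes with a mean of at least 10 CPM in the higher group, no overlap between the groups' libraries and an expected other-species share under 10%, leaving out clone-like symbols, and the 2 members of smallest p of each called list; some of these genes are not reported here. Folds against a group with at most 8 counts over its libraries are ratios of summed counts with exact conditional 95% intervals, which cover counting error only. Genes with more counts, such as FOS (35 in SUSP), LRRC32 (22 in SEP) and CD1C (27 in SEP), are given as fitted log2 changes. The shares of counts by species were compared with an exact two-sided permutation test. Replicate pairs were checked for duplicates: over 30 pairs the chi-square per degree of freedom ran from 1.74 to 8.58, so no pair agreed within sampling noise.

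The gene test was tested on simulated data, drawn from the real means, dispersions and library sizes with 200 changed genes. For human ADH vs SUSP (11346 genes, 20 runs) it recovered 42.7% of genes changed 1.25-fold, 77.5% at 1.5-fold, 91.5% at 2-fold and 99.4% at 4-fold, and 4.84% of calls were false on average (2.10% to 10.8%). For mouse ADH vs MS-5 (10761 genes, 20 runs) it recovered 52.2%, 86.1%, 96.1% and 100% at the same folds, and 6.44% of calls were false on average (3.51% to 13.0%), above the nominal 5%. A single run was made at first. Its mouse result of 13.0% exceeded the limit of 10% set for it, after which the number of runs was raised to 20, with that run kept, and the limit on single runs was dropped in favour of the average. A list shifted by 0.5 on the log2 scale was called in both simulations, and 0 of the other lists were. Genes were drawn independently of each other there. The simulations therefore cannot show how often the preset correlation gives false calls for lists of correlated genes.

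Alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter beyond 1 count, a filter of at least 5 CPM in at least 4 libraries, the replicate number as a block, removal of cross-species genes, subtraction of expected other-species counts, thinning to the lowest total, a change of at least 2-fold, a fit of the compared groups alone, and leaving out each library. A block of replicates 1 and 2 against 3 and 4, and leaving out libraries for the mouse share in SUSP vs SEP, were added after the data were seen. The human annotation at hand was GRCh38, another build than that of the counts, so no human coordinates are given. Mouse positions come from Gencode M21 on GRCm38, in which all 28 named mouse genes were found by Gene ID. Plots were drawn with matplotlib 3.10.9.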

Results

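Jeko-1 cells, a human mantle cell lymphoma line, were cultured alone or on MS-5 cells, a mouse bone marrow stromal line, and gene counts of polyadenylated RNA were obtained for both species in every library. The 16 libraries fall into 4 groups of 4 replicates: MS-5 cells alone (MS-5), Jeko-1 cells alone (SEP), the adherent fraction of the co-culture, which holds the stroma with the lymphoma cells attached to it (ADH), and the suspension fraction of the same kind of co-culture (SUSP). Because the lymphoma cells are human and the stroma is mouse, human counts describe Jeko-1 and mouse counts describe MS-5 within one mixed library. Human counts per library ran from 5306956 to 8103121 in SEP, 5553363 to 7824503 in ADH and 5466049 to 7449365 in SUSP. Mouse counts ran from 6067977 to 9332400 in MS-5 and 10801990 to 14120231 in ADH. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples. Values below are CPM, gene counts scaled by edgeR to the TMM-adjusted total of the species' own table, as mean ± SD with n = 4 libraries per group, and log2 fold changes are given with their standard error (SE).

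The first comparison asked what share of the gene counts in each co-culture fraction came from lymphoma and what share from stroma. A share of counts is not a share of cells, since RNA per cell was not measured. Human genes took 35.9% ± 2.61 of all gene counts in the ADH libraries (SD, n = 4) and 99.4% ± 0.0921 in the SUSP libraries (SD, n = 4). Mouse RNA gave 64.1% ± 2.61 of counts in ADH and 0.597% ± 0.0921 in SUSP. The difference of -63.5 percentage points was larger than the spread between libraries. An exact two-sided permutation test gave p = 0.0286, the smallest that the 70 assignments of 4 against 4 libraries allow. Cultures of a single species gave the background. Human counts made up 0.189% ± 0.0936 in MS-5 (SD, n = 4). In SEP there were 0.0783% to 0.125% mouse counts in 3 libraries and 0.797% in SEP replicate 2 (95% exact binomial interval 0.791% to 0.803%, which covers counting error only). The mouse share in SUSP was not shown to differ from that in SEP by the exact permutation test (p = 0.143). That outcome hung on SEP replicate 2: the SUSP libraries had 0.524% to 0.732% mouse counts, above the 3 other SEP libraries, and without replicate 2 the difference went from 0.325 to 0.5001 percentage points (exact permutation test, p = 0.0286, the smallest possible with 35 assignments). Leaving out any other library gave p from 0.143 to 0.257 in the same exact permutation test.

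**Figure D1:**
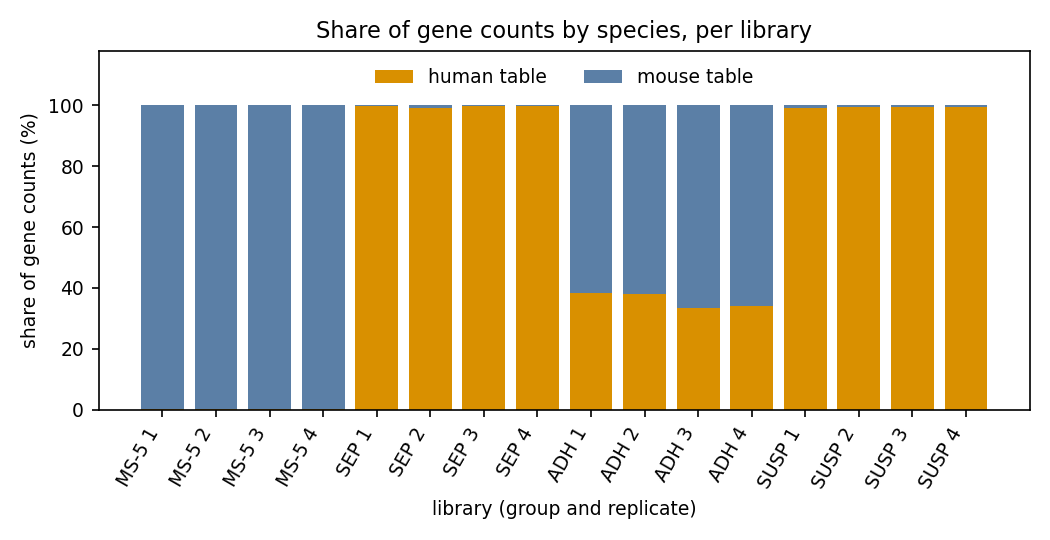
Share of gene counts (%) in the human and mouse tables for each of the 16 libraries, as stacked bars. The ADH libraries lie between 33.4% and 38.3% human, and the SUSP libraries between 99.3% and 99.5%.

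Human genes of the adherent fraction were first set against the suspension fraction, which asks what distinguishes lymphoma cells attached to stroma from those in the same co-culture that were not. TNF (Gene ID 7124), an inflammatory cytokine, had 162 ± 30.2 CPM in ADH and 7.23 ± 3.51 in SUSP, a log2 change of 4.54 (SE 0.23, adjusted p = 1.04e-12). The transcription factor EGR1 (Gene ID 1958) rose by 4.10 (SE 0.17, adjusted p = 4.91e-14), from 9.93 ± 3.27 to 172 ± 42.6 CPM, and FOS, EGR3 and EGR2 rose by 3.81 (SE 0.27), 3.72 (SE 0.19) and 3.24 (SE 0.19). Among genes that were lower, RAG1, a subunit of the recombinase that assembles antigen receptor genes, fell by 2.35 on the log2 scale (SE 0.12, adjusted p = 7.62e-13), and CXCR4, the receptor for the stromal chemokine CXCL12, fell by 1.05 on the log2 scale (SE 0.04), from 497 ± 13.3 to 240.3 ± 7.44 CPM. The protocadherin PCDH9 and the helicase PIF1 each had a log2 change of -1.07 (SE 0.09 and SE 0.11). The change was -1.17 for BMP3 (SE 0.10) and -1.24 for C10orf71 (SE 0.13).

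Of the gene lists, NF-kB targets rose as a group. Of 28 measured members 26 were higher, none was lower, and the median log2 change was 1.497 (camera adjusted p = 7.85e-102, and 0.000231 with an estimated correlation). Adjusted over the list alone, 27 were higher. CCL4 and CCL3, chemokines that attract T cells and monocytes, rose by 3.13 (SE 0.13) and 3.59 (SE 0.16), though both have near-identical copies in the genome, so how reads were divided among the copies is uncertain. Immediate-early genes, transcribed within minutes of a stimulus, rose in 21 of 24 measured members with none lower and a median of 1.62 (adjusted p = 2.91e-72, and 0.00153 with an estimated correlation), 22 when adjusted over the list alone. The phosphatase DUSP2 was an example, at 335 ± 39.98 CPM against 62.3 ± 7.68.

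Genes of G2/M and mitosis moved the other way. Of 30 measured, 25 were lower in ADH, none was higher, and the median was -0.42 (adjusted p = 1.66e-24, and 0.00600 with an estimated correlation), with 28 lower when adjusted over the list alone. PLK1, a mitotic kinase, and CENPF, a kinetochore protein, each had a log2 change of -0.70 (SE 0.05 and SE 0.06). Genes of G1/S and DNA replication did not pass the test (adjusted p = 0.730, 2 higher and 2 lower of 30).

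Smaller shifts appeared in stress and metabolic lists. In the unfolded protein response 11 of 22 members rose and 1 fell (median 0.19, adjusted p = 7.54e-06). The member of smallest p was HERPUD1, a factor of endoplasmic reticulum degradation, at 779.8 ± 4.01 CPM against 407 ± 3.05, a log2 change of 0.94 (SE 0.05). The chaperone HSPA5 had 0.36 (SE 0.04). Cholesterol biosynthesis and uptake had 12 of 23 higher and 1 lower (median 0.26, adjusted p = 9.32e-08). INSIG1, which restrains sterol synthesis, was at 0.90 (SE 0.09) and the synthetic enzyme SQLE at 0.45 (SE 0.05). Apoptosis regulators had 9 higher and 3 lower of 23 (adjusted p = 6.67e-07). The genes with the smallest p, BIRC3 at 1.52 (SE 0.09) and BCL2A1 at 1.91 (SE 0.12), are known to restrain cell death. The integrated stress response had 9 higher and 1 lower of 25 (adjusted p = 0.00642), including the tRNA synthetase WARS at 0.37 (SE 0.05) and DDIT4, an inhibitor of mTORC1, at 0.79 (SE 0.11).

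The unfolded protein response, cholesterol, apoptosis and stress response lists kept their call with an estimated correlation (adjusted p = 0.00835, 0.0333, 0.00754 and 0.0279). For 3 further lists the call was lost once the correlation between genes was estimated. Antigen presentation had 12 of 24 higher and none lower, with HLA-E at 0.46 (SE 0.05) and HLA-DRA at 0.27 (SE 0.04), genes whose relatives share reads, so their counts are uncertain (adjusted p = 0.0532 with an estimated correlation). Hypoxia and glycolysis had 9 of 28 higher and 1 lower, the glucose transporter SLC2A3 at 1.62 (SE 0.18) and the histone demethylase KDM3A at -0.32 (SE 0.06) (adjusted p = 0.0550 with an estimated correlation). B-cell receptor signalling and identity had 10 of 26 higher and 4 lower, with the phosphatase PTPN6 at 0.92 (SE 0.06) and the coreceptor CD72 at 0.54 (SE 0.07) (adjusted p = 0.251 with an estimated correlation).

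In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2081 of 11346 human genes differed between ADH and SUSP, 1000 higher and 1081 lower in ADH, of which 136 and 47 changed at least 2-fold. The lists of interferon-stimulated genes (7 higher and 1 lower of 25, adjusted p = 0.0529), MYC targets (0.0529), p53 targets (0.226), oxidative phosphorylation (0.116), stromal markers (5 measured, 0.304) and adhesion (0.649, with a median of 0.05 and a mean of 0.02 against a test in the lower direction) did not pass. Without a single library, the interferon list had an adjusted p of 0.0215 (ADH replicate 1), 0.0206 (ADH replicate 2), 0.0336 (SUSP replicate 3) and 0.0315 (SUSP replicate 4), and the MYC list of 0.0224, 0.0239, 0.0443 and 0.0213. TNF lies in the major histocompatibility complex (MHC), where counts were uneven between replicates: SUSP libraries held 16 to 56 TNF counts.

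**Figure D2:**
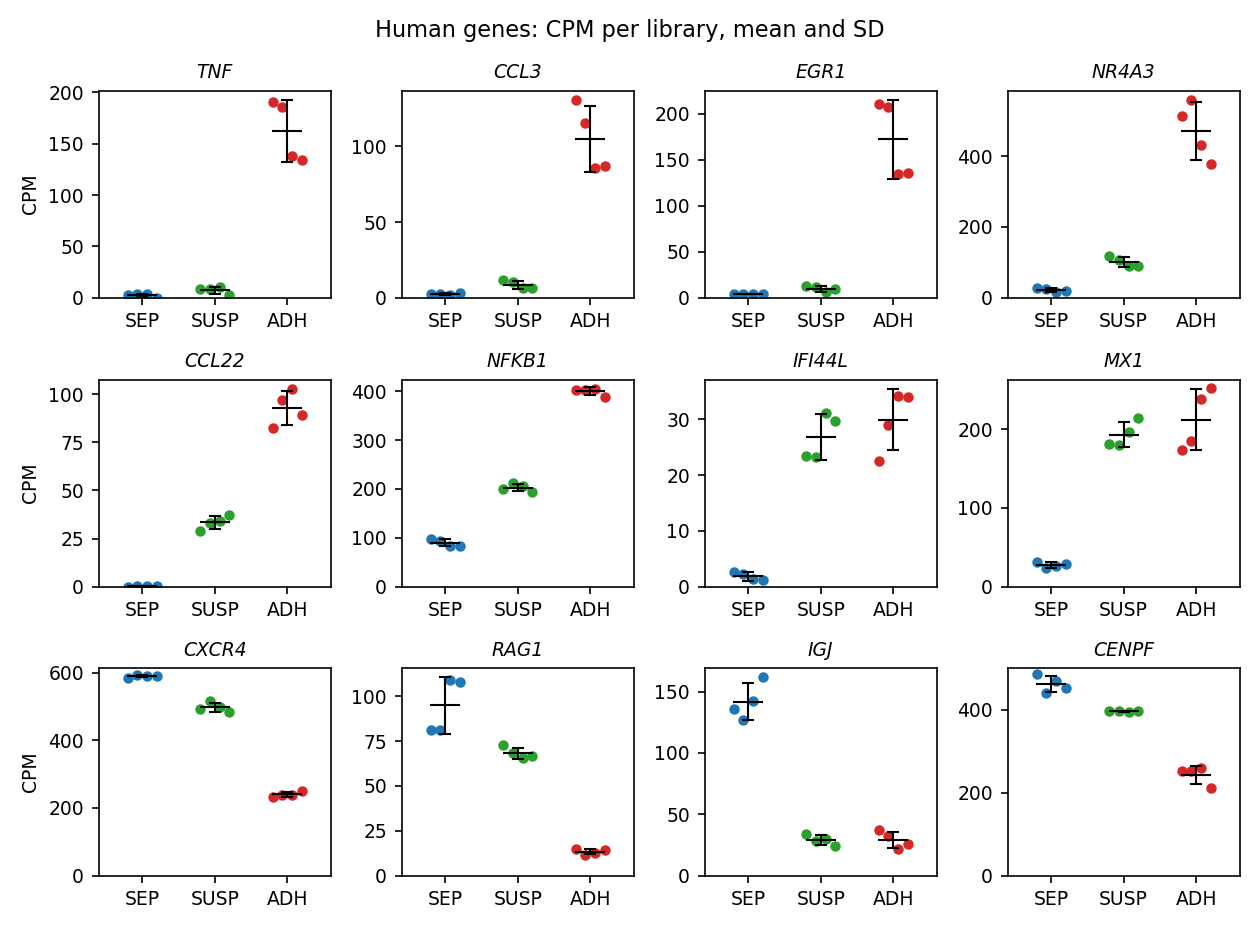
CPM of 12 human genes in each SEP, SUSP and ADH library (points), with the group mean and SD (black, n = 4). NFKB1 stands at 89.7, 203 and 400 CPM on average in SEP, SUSP and ADH, whereas IGJ is at 29.2 and 29.3 CPM in SUSP and ADH against 142 in SEP.

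The adherent fraction was next compared with Jeko-1 cells cultured alone, which asks how lymphoma cells recovered with the stroma differed from those that had none, with any effect of handling included. CCL22, a chemokine that binds CCR4, was nearly silent in SEP (4 counts over 4 libraries) and reached 92.7 ± 8.75 CPM in ADH, 612-fold higher with a 95% counting interval of 239 to 2248. EGR3 (8 counts in SEP) was 309.6-fold higher (157 to 718). VGF (7 counts), a neuropeptide precursor, was 68.5-fold higher (33.0 to 171) and PHLDA1 (6 counts) 66.1-fold higher (30.1 to 181). LRRC32, a cell surface receptor for latent TGF-beta, rose by 6.05 (SE 0.18, adjusted p = 4.77e-17), and TNF by 6.04 (SE 0.27), with 0 to 27 TNF counts in the SEP libraries.

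Of the genes that were lower, RAG1 fell by 2.82 on the log2 scale (SE 0.11, adjusted p = 2.37e-15), from 94.9 ± 15.7 to 13.5 ± 1.57 CPM. IGJ, the joining chain of secreted immunoglobulin, fell by 2.26 on that scale (SE 0.12). The log2 change was -2.94 for the adhesion receptor GPR56 (SE 0.20), -2.54 for SNTG2 (SE 0.13), -2.10 for CPNE5 (SE 0.07) and -2.01 for the secreted ligand BMP3 (SE 0.10).

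All 28 NF-kB targets measured were higher in ADH than in SEP (median 2.32, adjusted p = 6.01e-91, and 0.000231 with an estimated correlation), NFKB1 itself by 2.15 (SE 0.06, adjusted p = 2.70e-18). Immediate-early genes were higher in 21 of 24 members and lower in none (median 2.76, adjusted p = 2.03e-40). The orphan nuclear receptors NR4A3 and NR4A1 rose by 4.46 (SE 0.14) and 2.97 (SE 0.09). Interferon-stimulated genes, which did not pass between the co-culture fractions, were higher in 22 of 25 and lower in 1 (median 1.65, adjusted p = 3.22e-29, and 0.000403 with an estimated correlation). IFITM1 rose by 2.54 (SE 0.09), with the caution that IFITM genes resemble each other closely.

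Genes of G2/M and mitosis were lower in 29 of 30 (median -0.59, adjusted p = 8.60e-20, and 0.00845 with an estimated correlation), CENPF by a log2 change of -0.92 (SE 0.06) and the checkpoint kinase BUB1 by -0.82 (SE 0.05). Antigen presentation had 19 of 24 higher and none lower (median 0.42, adjusted p = 6.17e-07), with HLA-E at 1.15 (SE 0.05) and HLA-DRA at 0.55 (SE 0.04). Apoptosis regulators had 12 higher and 3 lower of 23 (adjusted p = 3.81e-07), with BCL2A1 going from 1.89 ± 0.409 to 63.4 ± 10.9 CPM. The unfolded protein response had 15 higher and 3 lower of 22 (adjusted p = 7.37e-05, HERPUD1 at 1.86, SE 0.06). Hypoxia and glycolysis had 18 higher and 2 lower of 28 (adjusted p = 0.000607, PKM at 0.48, SE 0.04), and the integrated stress response 13 higher and 4 lower of 25 (adjusted p = 0.0110, the amino acid transporter SLC7A5 at 0.85, SE 0.05). With an estimated correlation the adjusted p of these lists was 0.0244, 0.00754, 0.0151, 0.00942 and 0.0351, in the order given.

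Calls on 4 lists were lost with an estimated correlation. MYC targets and ribosome biogenesis had 23 of 27 higher and 1 lower, NOP16 at 0.69 (SE 0.07) and TFRC, the transferrin receptor, at 0.46 (SE 0.05) (adjusted p = 0.0852 with an estimated correlation). Cholesterol genes had 14 of 23 higher and 1 lower, SQLE at 0.86 (SE 0.05) and DHCR7 at 0.78 (SE 0.07) (adjusted p = 0.159 with an estimated correlation). Adhesion, migration and homing split, with 11 higher and 9 lower of 23. CXCR4 fell by 1.30 on the log2 scale (SE 0.04) and the lymph node homing receptor CCR7 rose by 1.77 (SE 0.09) (adjusted p = 0.0516 with an estimated correlation). The B-cell list also split, 13 higher and 9 lower of 26, with PTPN6 at 2.04 (SE 0.06) and MS4A1, which encodes CD20, at 0.88 (SE 0.05) (adjusted p = 0.251 with an estimated correlation).

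By edgeR's quasi-likelihood test 4994 of 11346 genes differed between ADH and SEP, 2494 higher and 2500 lower, with 473 and 213 changing at least 2-fold. Not passing were the lists of G1/S (1 higher and 10 lower of 30, adjusted p = 0.0894), oxidative phosphorylation (0.0926), p53 targets (0.649) and stromal markers (0.398). The G1/S list had an adjusted p of 0.0483 without SEP replicate 4 and 0.0446 without ADH replicate 2, and oxidative phosphorylation of 0.0460 without SEP replicate 2, the library with 0.797% mouse counts.

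**Figure D3:**
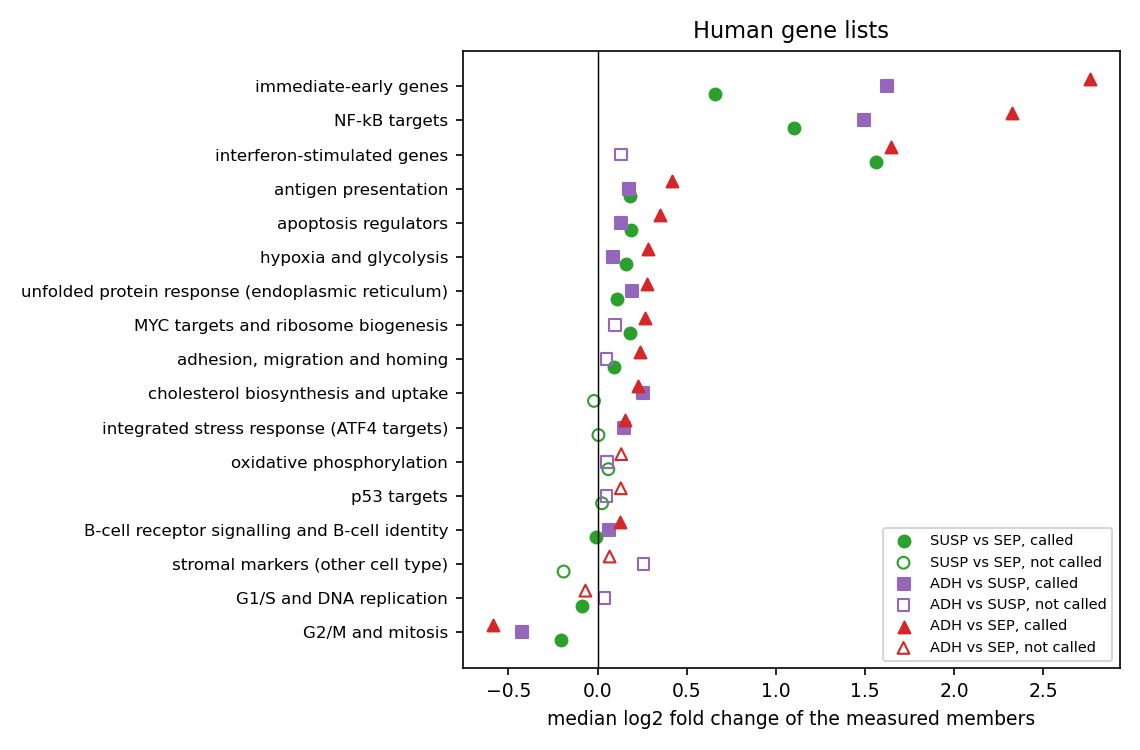
Median log2 fold change of the measured members of each of the 17 human gene lists (rows) in the 3 human comparisons, with filled symbols where camera with the preset correlation called the list at an adjusted p under 0.05. Interferon-stimulated genes sit at 1.56 in SUSP vs SEP and 1.65 in ADH vs SEP, and immediate-early genes at 0.66 and 2.76.

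Jeko-1 cells in the suspension of the co-culture were then compared with Jeko-1 cells alone, which asks what changed in lymphoma cells that shared a dish with stroma but were not attached. Of interferon-stimulated genes, 23 of 25 were higher and none lower (median 1.56, adjusted p = 7.57e-65, and 9.26e-05 with an estimated correlation). MX1, an antiviral GTPase, went from 27.4 ± 3.50 to 193 ± 16.0 CPM, a log2 change of 2.83 (SE 0.12, adjusted p = 4.80e-14), and IFI44L rose by 3.84 (SE 0.22). NF-kB targets had 23 of 28 higher and none lower (median 1.10, adjusted p = 4.77e-49, and 0.00110 with an estimated correlation). CCL22 was 221-fold higher on 4 counts in SEP (95% counting interval 85.9 to 812), and NFKB1 rose by 1.17 (SE 0.06).

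Other genes that rose were LRRC32 at 4.19 (SE 0.23), the lipid antigen presenting molecule CD1C at 3.61 (SE 0.21), the regulators of G protein signalling RGS1 at 3.36 (SE 0.19) and RGS2 at 1.73 (SE 0.09), and VGF (52.2-fold, 25.1 to 131, on 7 counts in SEP). IGJ fell by 2.28 on the log2 scale (SE 0.12). The log2 change was -1.79 for SNTG2 (SE 0.12), -1.62 for CPNE5 (SE 0.07), -1.33 for the potassium channel KCNN3 (SE 0.15), -1.28 for DERL3 (SE 0.19) and -1.26 for the kinase FGR (SE 0.16). RGS1 and RGS2, which dampen chemokine receptor signals rather than bind other cells, belong to the adhesion, migration and homing list, in which 9 were higher and 3 lower of 23 (adjusted p = 3.83e-06, and 0.00377 with an estimated correlation). Apoptosis regulators (9 higher and 2 lower of 23, adjusted p = 9.28e-05), hypoxia and glycolysis (11 higher and 1 lower of 28, 0.000430) and antigen presentation (11 higher and 1 lower of 24, 2.35e-05) also kept their call when the correlation was estimated (adjusted p = 0.0211, 0.00910 and 0.0469). Their members included BCL2A1 at 3.12 (SE 0.22), CFLAR at 1.02 (SE 0.09), PKM at 0.33 (SE 0.04), HLA-E at 0.69 (SE 0.05) and HLA-DRB1, which resembles other HLA-DRB genes, at 0.49 (SE 0.05).

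Immediate-early genes were higher in 12 of 24 and lower in 1 (median 0.66), with NR4A3 at 2.24 (SE 0.15) and NR4A1 at 1.08 (SE 0.10) (adjusted p = 0.0964 with an estimated correlation). G2/M genes were lower in 14 of 30 and higher in none (median -0.20), NUSAP1 by a log2 change of -0.41 (SE 0.05) (adjusted p = 0.0674 with an estimated correlation). G1/S genes were lower in 8 of 30, among them the transcription factor E2F2 at -0.46 (SE 0.07) and the ribonucleotide reductase subunit RRM1 at -0.23 (SE 0.04) (adjusted p = 0.382 with an estimated correlation). MYC targets were higher in 16 of 27, with RRP12 at 0.40 (SE 0.06) (adjusted p = 0.0534 with an estimated correlation). The unfolded protein response had 8 higher and 2 lower of 22, HERPUD1 at 0.92 (SE 0.06) against the ubiquitin ligase SYVN1 at -0.47 (SE 0.07) (adjusted p = 0.0940 with an estimated correlation). The B-cell list had 7 higher and 6 lower of 26, a median of -0.01 and a mean of 0.10, with a test in the higher direction (adjusted p = 0.418 with an estimated correlation). Without SEP replicate 3, SEP replicate 4, SUSP replicate 1 or SUSP replicate 2 its adjusted p at the preset correlation was 0.0647, 0.0599, 0.124 and 0.0954.

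In total 2104 of 11346 genes differed between SUSP and SEP by edgeR's quasi-likelihood test, 1169 higher and 935 lower, with 251 and 45 changing at least 2-fold. Cholesterol genes (3 higher and 1 lower of 23, adjusted p = 0.892, with a median of -0.02 and a test in the higher direction), the integrated stress response (0.114), oxidative phosphorylation (0.219), p53 targets (0.730, with a median of 0.03 and a test in the lower direction) and stromal markers (0.669, with a median of -0.19 and a mean of 0.33) did not pass.

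The human libraries separated by group along the first principal component of log2 CPM, with SUSP in the middle. Of the 4994 genes that differed between ADH and SEP, 4727 had the same sign in SUSP vs SEP, 1871 were also called there in the same direction and 10 were called in the opposite direction. Both comparisons share the SEP libraries. Unchanged groups simulated against shared libraries gave 0 such genes on average over 20 runs. With no gene differing there, this cannot show how far shared libraries raise the overlap of genes that differ. Independent lists of these sizes would share 257 higher and 206 lower genes. Dividing the SEP libraries between the comparisons gave 1034 to 1330 over 6 splits. Each comparison then had fewer libraries, which can itself lower the number of calls.

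**Figure D4:**
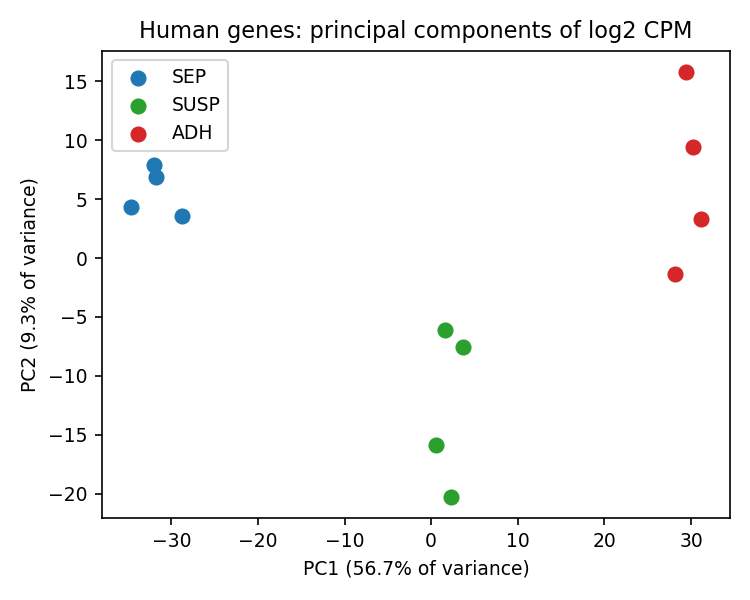
The first and second principal components of log2 CPM of human genes, 1 point per library, with the share of variance on each axis. SEP libraries lie between -34.7 and -28.7 on the first component, SUSP between 0.585 and 3.63, and ADH between 28.1 and 31.2.

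Genes that set the adherent cells apart from both other states were counted as those changed in ADH against SUSP and against SEP with the same sign. There were 1862, 917 higher and 945 lower, and 11 more were called in opposite directions. TNF, EGR3 and BCL2A1 were among those higher in both comparisons, and RAG1, CXCR4, BMP3 and CENPF among those lower in both. Both comparisons use the same ADH libraries, which can raise the overlap. Simulated unchanged groups gave 0.1 genes on average and at most 1 in 20 runs. No gene differed in that simulation, so it cannot show how far shared libraries raise the overlap of genes that differ. Independent lists of these sizes would share 220 higher and 238 lower genes. When 2 ADH libraries were used against SUSP and the other 2 against SEP, 811 to 1185 genes were shared over 6 splits. Fewer libraries per comparison can also lower the number of calls, so this drop does not measure the sharing alone.

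The last comparison took the mouse genes and asked how stromal cells of the co-culture differed from stroma alone. Attachment cannot be told apart there from sharing a dish, as no group held stroma with unattached lymphoma cells only. Pde1b (Gene ID 18574), a cyclic nucleotide phosphodiesterase, rose by 2.14 on the log2 scale (SE 0.17, adjusted p = 5.55e-06), from 2.91 ± 0.736 to 13.1 ± 1.76 CPM. Hes1, a transcriptional repressor induced by Notch signalling, rose by 1.96 (SE 0.32), the collagenase Mmp13 by 1.91 (SE 0.28), the matrix protein Smoc1 by 1.254 (SE 0.16), the collagen chain Col5a3 by 1.10 (SE 0.08) and the NF-kB subunit Relb by 0.85 (SE 0.16). Cth, an enzyme of cysteine synthesis, fell by 0.87 on that scale (SE 0.12), and the log2 change was -0.81 for Vnn1 (SE 0.12) and -0.69 for the integrin Itgb7 (SE 0.13). It was -0.78 for Firre (SE 0.16), -0.58 for the glycine transporter Slc6a9 (SE 0.14) and -0.55 for Ddx26b (SE 0.12), but none of these 3 kept its call in every fit without a single library. The adjusted p reached 0.0505 to 0.0595 for Firre (MS-5 replicates 1 and 2, ADH replicates 1 and 2), 0.0571 to 0.135 for Slc6a9 (each MS-5 replicate, ADH replicates 1 and 2) and 0.0572 to 0.0743 for Ddx26b (MS-5 replicates 2 and 4, ADH replicates 1 and 2).

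Of the lists, 3 kept their call with an estimated correlation. Integrated stress response genes were lower in 9 of 24 and higher in none (median -0.24, adjusted p = 5.43e-18, and 0.00466 with an estimated correlation), including Cth and the serine synthesis enzyme Psat1 at -0.33 (SE 0.05). Adjusted over the list alone, 16 were lower and 2 higher. NF-kB targets were higher in 6 of 25 and lower in none (median 0.14, adjusted p = 1.37e-09, and 0.0119 with an estimated correlation), 10 higher and 3 lower when adjusted over the list alone. The members of smallest p were the monocyte chemokines Ccl2 at 0.44 (SE 0.05) and Ccl7 at 0.40 (SE 0.06). Notch and Wnt targets were higher in 3 of 6 measured (median 0.50, adjusted p = 6.03e-16, and 0.00262 with an estimated correlation), with Wisp2 at 0.79 (SE 0.06) and the Notch ligand Jag1 at 0.84 (SE 0.11). Only 6 of the 24 members of this list were measured. Its estimated correlation was -0.157, below the preset 0.01, so the estimate allowed for no more correlation than the preset did.

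Calls on 6 mouse lists were lost with an estimated correlation. Extracellular matrix genes were higher in 3 of 21, with Col6a2 at 0.75 (SE 0.11) and Col6a1 at 0.65 (SE 0.11) (adjusted p = 0.104 with an estimated correlation). Matrix-degrading enzymes were higher in 4 of 17, Mmp13 and Adamts2 among them (adjusted p = 0.0673 with an estimated correlation). Cholesterol genes were higher in 4 of 23, with Sqle at 0.38 (SE 0.08) (adjusted p = 0.135 with an estimated correlation). Hypoxia and glycolysis had 6 higher and 1 lower of 24, with Pdk1 at 0.48 (SE 0.06) and Pfkl at 0.36 (SE 0.05) (adjusted p = 0.116 with an estimated correlation). Adipogenic genes were higher in 2 of 16 (Plin2 at 0.22, SE 0.05, and Scd1 at 0.49, SE 0.11; adjusted p = 0.302 with an estimated correlation). Of the myofibroblast genes 1 of 23 was higher, Tpm2 at 0.24 (SE 0.05), while Tgfb1 had 0.32 (SE 0.08, adjusted p = 0.0648); for the list, adjusted p = 0.336 with an estimated correlation. At the preset correlation the adipogenic list had an adjusted p of 0.0563, 0.0673, 0.154 and 0.0893 without MS-5 replicate 1, MS-5 replicate 2, ADH replicate 3 or ADH replicate 4, and the myofibroblast list of 0.0824 without MS-5 replicate 3 and 0.0571 without ADH replicate 1.

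By edgeR's test over all genes none of 14 mouse interferon-stimulated genes (adjusted p = 0.289), 25 immediate-early genes (0.563), 30 G2/M genes (0.839), 29 G1/S genes (0.563), 22 unfolded protein response genes (0.839), 22 p53 targets (0.0572) or 30 oxidative phosphorylation genes (0.433) was called. Chemokines and cytokines (0.136), osteogenic genes (0.194) and markers of blood cells (5 measured, 0.194) did not pass as lists. The p53 list had an adjusted p of 0.0107 without MS-5 replicate 3, 0.0261 without ADH replicate 2 and 0.0398 without ADH replicate 4, and the chemokine list of 0.0457 without MS-5 replicate 3. By edgeR's quasi-likelihood test 161 of 10761 mouse genes differed, 112 higher and 49 lower, of which 8 and 1 changed at least 2-fold, and 1215 had an unadjusted p under 0.05. The count depended on single libraries: it was 69 without MS-5 replicate 4, 85 without ADH replicate 2 and 107 without MS-5 replicate 2. It also depended on the replicate numbers: with the number as a block it was 317 (202 higher and 115 lower), and with a block of replicates 1 and 2 against 3 and 4, chosen after the data were seen, 316. Setting replicates 1 and 2 of both groups against replicates 3 and 4 gave 89 genes. Leaving out single libraries also ended the call of Plin2 (adjusted p 0.0509 to 0.103; all but ADH replicate 3), Tpm2 (0.0527 to 0.123; each MS-5 replicate, ADH replicates 2 and 4), Scd1 (0.0947 to 0.141; MS-5 replicates 1, 2 and 4, ADH replicates 3 and 4) and Sqle (0.0528 to 0.0637; MS-5 replicates 1, 2 and 4).

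On the mouse genome (GRCm38, Gencode M21), Pde1b lies on chromosome 15 from 103503034 to 103530052 on the plus strand, Col5a3 on chromosome 9 from 20770050 to 20815067 on the minus strand, Mmp13 on chromosome 9 from 7272514 to 7283331 on the plus strand, and Hes1 on chromosome 16 from 30064384 to 30067796 on the plus strand. Cth lies on chromosome 3 from 157894248 to 157925077 on the minus strand, and Wisp2, named Ccn5 in that annotation, on chromosome 2 from 163820861 to 163833146 on the plus strand. Counts cover whole genes, so no exon or untranslated region is singled out.

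**Figure D5:**
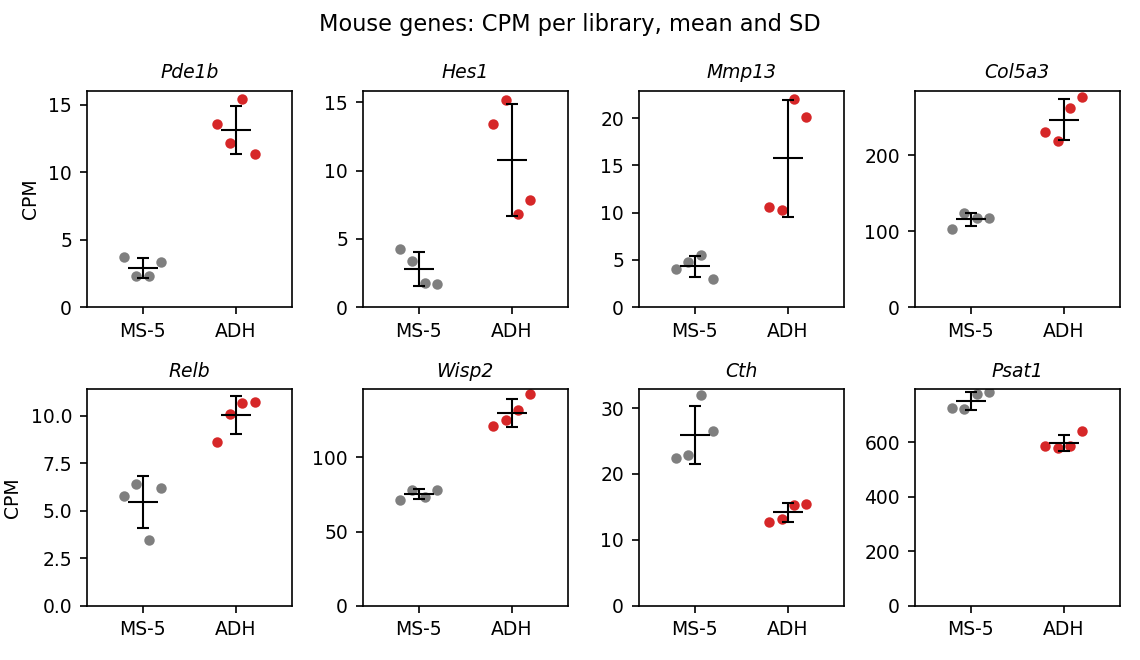
CPM of 8 mouse genes in each MS-5 and ADH library (points), with the group mean and SD (black, n = 4). Col5a3 averages 116 CPM in MS-5 and 247 CPM in ADH, and Cth 25.9 and 14.2 CPM.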

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

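The tests of the suspension fraction and of the immediate-early genes below, and that of counting noise for TNF, were chosen only after the results were seen. The other tests of TNF, LTA and LTB also concern a pattern seen in the counts. That of NF-kB activity was set on SEP replicate 4, the SEP library with 0 TNF counts.

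Lymphoma cells in suspension lay between those cultured alone and those attached to stroma, but not at the same distance for every gene list. If SUSP held a fixed share of cells like those in ADH and the rest like those in SEP, every list would give the same share. Fitted to interferon-stimulated genes the share was 73.9% to 92.2% over the SUSP libraries, fitted to NF-kB targets 18.5% to 23.3% and to immediate-early genes 7.16% to 18.8%. The lowest interferon share exceeded the highest immediate-early share by 0.551 (as a fraction). This argues against a fixed share of cells with the levels measured in ADH. For immediate-early genes those levels may include handling, which cannot be told apart from attachment. A share of attached cells whose levels differed before handling therefore stays open. Misassigned mouse reads (median expected share 0.277% of the genes changed alike) and depth (1755 such genes after thinning to one depth, against 1871) do not account for the place of SUSP between SEP and ADH. A response of unattached cells to the co-culture may underlie it, as a hypothesis found on these data. Jeko-1 cells held apart from the stroma by a porous membrane in a shared dish would test it.

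Immediate-early genes were far higher in ADH than in either other state, and such genes can also respond to the handling of cells before lysis. Misassigned mouse reads are excluded (median expected share 0.103% of members, at most 1.97%). Handling of the adherent layer as the cause of the whole rise over SEP predicts no member higher in SUSP than in SEP. Of 24 measured members 12 were higher there and 1 was lower, with a median of 0.66 against 2.76 in ADH. The list lost its call there with an estimated correlation (camera adjusted p = 0.0964). These members argue against handling only if the suspension held no handled cells of the adherent layer. The labels do not settle that, so no conclusion is drawn. Handling as the cause of the further rise from SUSP to ADH cannot be told apart from attachment, because the labels do not say how the fractions were separated and any difference in handling would coincide with the fraction. Heat-shock genes had a median log2 change of 0.0114 between these fractions, with 1 of 9 called higher (HSPA8 at 0.15, SE 0.04), and that bears on heat-shock genes alone.

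Counts of TNF, LTA and LTB, neighbours in the MHC, were uneven between replicates: TNF had 15, 27, 23 and 0 counts in the SEP libraries, LTA 0, 14, 10 and 0, and LTB 0, 10, 24 and 8. Counting noise cannot be told apart from the spread between cultures by the test made (exact multinomial test of TNF, p = 6.08e-06), which takes reads as independent molecules, because every replicate pair varied by more than counting noise (1.74 to 8.58 as chi-square per degree of freedom). Lower NF-kB activity in SEP replicate 4 is argued against by its 24 other NF-kB targets, whose median differed from the other SEP libraries by -0.15 on the log2 scale. A candidate explanation is reads shared with other copies of the MHC in a reference. For 90 other genes of the region, spread between replicates was measured as residual deviance per degree of freedom around the fitted dispersion trend. Its median was 2.53 times that of matched genes, at percentile 100 of random sets matched on expression. No other biological explanation was tested.

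The change from culture alone to ADH was called different between the species for 8 of 11 lists measured in both, by a permutation of labels within each species (4900 assignments). The difference was the mean log2 change in Jeko-1 (ADH minus SEP) minus that in MS-5 (ADH minus MS-5). The change in Jeko-1 includes any effect of handling the adherent layer, which cannot be told apart from co-culture here. The integrated stress response differed by 0.42 (adjusted p = 0.00449), from 0.20 in Jeko-1 to -0.23 in MS-5. The others were NF-kB targets at 2.69, immediate-early genes at 2.45, interferon-stimulated genes at 1.68, the unfolded protein response at 0.26, p53 targets at 0.14, G1/S genes at -0.14 and G2/M genes at -0.59, each with a permutation adjusted p of 0.0499. Cholesterol (0.766), hypoxia (0.0777) and oxidative phosphorylation (0.0554) were not shown to differ. The permutations include large effects of one species in their own chance range. They also treat the species as independent although both were read from the same ADH libraries, and the measured members of a list differ between species (25 human and 14 mouse interferon-stimulated genes), so the calls at 0.0499 are weak.

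Among 263 groups of 4 libraries tested for a library far from the others, 13 had one, about as many as the 5% of groups that chance gives. Single cases below may therefore be chance. SEP replicate 2 had 0.797% mouse counts against 0.0783% to 0.125% in the other SEP libraries. ADH replicate 4, the ADH library with the fewest human counts, had a count for 16001 human genes against 13930 to 14225. It also stood apart in CENPF (211 CPM against 252 to 260), NFKB1 (388 against 403 to 405), Ccl7 (223 against 197 to 201) and Psat1 (641 against 578 to 588). The remaining human cases were SQLE in SEP replicate 1 (254 CPM against 279.6 to 283), MS4A1 in SUSP replicate 4 (702 against 796 to 801) and NUSAP1 in SEP replicate 3 (381 against 351 to 353). The remaining mouse cases were Vnn1 in MS-5 replicate 4 (14.8 against 11.8 to 11.9), Itgb7 in MS-5 replicate 1 (23.0 against 17.4 to 18.0), Scd1 in MS-5 replicate 3 (74.4 against 53.03 to 56.0) and Jag1 in MS-5 replicate 2 (11.2 against 9.17 to 9.49).

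For each count of changed genes the real grouping gave the most genes, at a share of splits under 0.05, which argues against chance assignment of libraries to groups. A share of 1 in 35 is the smallest that 35 splits allow, so chance is not excluded. Splits that mix groups with a real difference take it into their spread, so their low counts were to be foreseen. Of 35 splits of the libraries, no split other than the real gave more than 1 gene for ADH vs SUSP (2081), 0 for ADH vs SEP (4994) and 0 for SUSP vs SEP (2104), and of 100 relabelings none but the real gave more than 0 genes changed against both (1862). For the mouse genes (161) the highest other split gave 89, setting replicates 1 and 2 of MS-5 and ADH against replicates 3 and 4, which points to a structure of the samples along the replicate numbers.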

How the results depend on the processing

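The block of replicates 1 and 2 against 3 and 4, and leaving out libraries for the mouse share in SUSP vs SEP, were chosen after the data were seen, and the other alternatives before. No list or named gene reversed under any alternative run. Of the genes called in ADH vs SEP 1 had the opposite sign with expected other-species counts subtracted (4943 of 4944 shared calls kept it). Which direction held more genes changed in 3 counts with DESeq2 size factors: from 1000 higher and 1081 lower to 1072 and 1040 for ADH vs SUSP, from 2494 and 2500 to 2537 and 2445 for ADH vs SEP, and from 917 and 945 to 976 and 907 against both. The Wald test, thinning, a 2-fold change and leaving out ADH replicate 1, 2 or 4 also changed it in these 3, and further alternatives in some of them. The counts of changed genes stayed within 1.5 times their value under DESeq2 size factors, the DESeq2 Wald test (1934, 4660, 1937, 1739 against both, and 219 mouse genes), other filters, removal or subtraction of cross-species counts, thinning and a fit of the compared groups alone.

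Demanding a 2-fold change left 183 genes for ADH vs SUSP (136 higher and 47 lower), 686 for ADH vs SEP (473 and 213), 296 for SUSP vs SEP (251 and 45), 163 against both (129 and 34) and 9 mouse genes (8 and 1), fewer by construction. Leaving out each library gave 1658 to 2108 genes for ADH vs SUSP, 4456 to 4810 for ADH vs SEP, 1704 to 2045 for SUSP vs SEP, 1507 to 1887 against both, 69 to 145 mouse genes (the lowest without MS-5 replicate 4), a difference in human share of -64.3 to -62.6 points, 34 to 38 called human lists and 8 to 10 mouse lists. Without SEP replicate 2 the counts were 4691, 2045 and 1837.

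Of 35 called human lists 22 kept a call with an estimated correlation, and of 9 mouse lists 3. A correlation above the preset 0.01 cannot be the cause of every lost call. The estimate was 0.00325 for hypoxia in ADH vs SUSP, 0.00339 for adhesion in ADH vs SEP and -0.000586 for mouse matrix-degrading enzymes. The cause of these losses was not tested. With fry 45 human and 5 mouse lists were called, and the cause was not tested. Named human genes kept their call under every alternative other than the 2-fold change. Thinning ended the calls of Tpm2 (adjusted p = 0.0535) and Plin2 (0.0761), and Tgfb1 was called by DESeq2 (0.0220) and with no filter (0.0103).

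Samples of the same replicate number were not paired by the labels, and their deviations correlated by 0.0993 to 0.226 between ADH and SUSP, -0.0229 to 0.116 between ADH and SEP, 0.0332 to 0.0998 between SUSP and SEP and 0.0739 to 0.119 between the mouse groups. Of 8 libraries 6, 4, 5 and 4 correlated best with their own number, where each had 4 numbers to match. A link by replicate number is therefore not excluded. The permutation test of species shares and the splits treat libraries as exchangeable and do not allow for such a link. The replicate number as a block gave 2521, 5326, 2447 and 2237 human genes and 317 mouse genes, among them all 161, and 33 human and 9 mouse lists. It ended the calls of hypoxia in ADH vs SUSP (adjusted p = 0.0518) and the B-cell list in SUSP vs SEP (0.0549), and Tgfb1 was called (0.00972). The block of replicates 1 and 2 against 3 and 4 gave 316 mouse genes, again with all 161, and called Tgfb1 (0.0186) and the mouse p53 list (0.0447). The cause was not tested. A 1.5-fold change was recovered in 77.5% of simulated genes for ADH vs SUSP.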

Other observations

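The gene sets here were chosen after their values were seen, and the values are given with no test of an explanation.

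Of single genes in the lymphoma cells, CTLA4, an inhibitory receptor, had 0 counts in SEP, 82 in ADH and 89 in SUSP. With SEP set to a floor of 3 counts over the group, this is 26.3-fold and 29.8-fold higher (exact 95% lower limits 20.9 and 23.7, for counting error only). TNFRSF9, a costimulatory receptor, had 0 counts in SEP, 109 in ADH and 19 in SUSP, 34.98-fold and 6.35-fold higher at the same floor (lower limits 28.0 and 4.68). PDCD1, which encodes PD-1, had 84.7 ± 2.79 CPM in ADH, 43.0 ± 5.01 in SUSP and 11.4 ± 2.68 in SEP (SD, n = 4). The costimulatory ligands CD86 and ICOSLG rose by 1.96 (SE 0.08) and 2.22 (SE 0.09) in ADH vs SEP and by 1.503 (SE 0.08) and 1.48 (SE 0.09) in SUSP vs SEP. CD276, on 8 counts in SEP, was 41.4-fold higher in ADH (95% counting interval 20.8 to 96.7).

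IRF4, a transcription factor of activated B cells, rose by 1.05 (SE 0.08) in ADH vs SUSP and by 1.37 (SE 0.08) in ADH vs SEP, while PRDM1, a regulator of plasma cells, had 0.09 and 0.16 and was not called in edgeR's test. In the stroma, single genes of one-carbon and amino acid enzymes that were lower in ADH than in MS-5 were Aldh1l2 at -0.47 (SE 0.07), Gpt2 at -0.47 (SE 0.07), Pck2 at -0.36 (SE 0.05) and Ass1 at -0.39 (SE 0.09).

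Interferon genes themselves had few counts. IFNB1 had 6 counts over the 4 ADH libraries, 1 in SUSP and 0 in SEP, IFNW1 had 13 in SEP, 7 in ADH and 13 in SUSP, and each of 10 mouse interferon genes had 0 counts in every library.

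The mouse counts of SEP replicate 2 had a Spearman correlation of 0.874 with MS-5 across 10779 genes, which are not independent replicates. The other SEP libraries had 0.515 to 0.561 and the SUSP libraries 0.783 to 0.839, with mouse counts of 5047 to 6639 and 30868 to 48666 against 65116 in SEP replicate 2.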
